A study of Meleagris gallopavo with 8 samples.

How the data were processed

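Messenger RNA was profiled in the pectoralis major (breast) muscle of turkeys of a random-bred line, slaughtered at 22 weeks of age. Per the labels' protocols, 43 birds were raised by conventional husbandry and breast meat was classed by how much marinade it had taken up at 24 h after slaughter. Meat with high uptake was called normal and meat with low uptake was called pale, soft and exudative (PSE), a quality defect in which the meat is light in colour and holds water poorly. The series holds 8 samples, 4 normal and 4 PSE. Total RNA was isolated from frozen muscle, 10 µg of RNA with an integrity number of at least 8 went into each library, and 2 libraries were run per lane of an Illumina GAIIx instrument, per the labels. Which libraries shared a lane, the read length and the strand protocol were not given in the sources used here.

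TopHat, Cufflinks, HTSeq and DESeq are named in the submitters' processing notes, without versions, roles or order. The genome build and the reference annotation were not given in the sources used here. The transcript annotation deposited by the authors was used: it lists the exons of merged transcripts, names Cufflinks as the source of every line, and gives each transcript a locus, a class against the nearest reference transcript, a gene name where there is one, and the name of the sample assembly it is credited to. Its reference transcripts carry Ensembl turkey identifiers. The annotation is called curated, and the rule of that curation is not given in the sources used here. Coordinates below are 1-based and are those of the file.

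A deposited table of counts per locus was not used. Its 8 columns of values have no names, so none of them can be tied to a sample by name. The labels number the samples 1 to 8, but nothing in the sources used here says that the columns follow those numbers, and a column's place in the table was not taken as its identity. The comparison of expression between PSE and normal muscle that was planned before the data were examined was therefore not made, no fold change is reported, and the depth of each library is unknown here. The gene lists, the genes to be named and the test of each list against expression were fixed before the data were examined. All tests reported here were chosen after that, because the planned tests needed the counts.

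The annotation was parsed in Python 3.11.15 with pandas 2.3.3 and NumPy 2.4.6. A transcript's class was read as the Cufflinks suite defines it: an exact match has the same intron chain as a reference transcript, a contained transcript fits inside one, and a variant shares at least 1 splice junction with one but differs elsewhere. A gene was called assembled when its name stood on at least 1 transcript of these 3 classes. The other classes cover other overlaps on the same strand, single exons that run into introns, transcripts inside introns, transcripts close to a gene, transcripts on the opposite strand of an exon, and introns opposite an intron. The rest carry a dot in place of a class letter and are called transcripts with no class. What the dot stands for in this annotation is not given in the sources used here.

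Of the 30 gene lists, 28 had at least 5 members in the background and were tested. The background was the 11646 protein-coding gene symbols of a RefSeq table of the turkey assembly Turkey_5.1, without placeholder symbols and mitochondrial genes. That table served only for names, and none of its coordinates were used. A list member is called measurable below when its symbol was in this background. The annotation can use another symbol, so a measurable gene could count as unassembled through its name alone. For example, PKM was in the background with no locus under that symbol, while PKM2 was assembled and outside the background. The shares of a list and of other genes therefore depend partly on how far the names of RefSeq and of the annotation match. Of the 7360 assembled gene names, 5815 (79.0%) were in the background, and 662 of the 980 list symbols (67.6%) were. Each list was compared with the rest of the background by a two-sided Fisher's exact test (SciPy 1.17.1), with Benjamini-Hochberg adjustment over the 28 lists and an adjusted p under 0.05 as the threshold. A list's share carries an exact (Clopper-Pearson) 95% interval. Genes are not independent replicates, lists share members, and a gene can be missing because it was not expressed, not assembled, named otherwise or absent from the annotation as used here, so these tests describe this one merged assembly. The same test compared, among assembled genes, those with and without a variant transcript, and a Mantel-Haenszel test over 5 classes of exon number (statsmodels 0.14.6) was the alternative. Exon number was the most exons on any exact, contained or variant transcript of the gene. It can come from the variant under test, so the structure of the full gene was not controlled for.

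Single-exon transcripts on the opposite strand of an exon were set against the exons of spliced transcripts (at least 2 exons) on the other strand. For each, the share of its length covered by those exons was computed, with the mean share over 20 random placements that touch the same exon. Both procedures were tested on simulated data. With 50% of 11646 genes set as assembled and changed lists set to 90%, 98% of the changed lists with at least 20 members were recovered over 20 simulations and 2.22% of unchanged lists were called. Genes were drawn independently and without name mismatches, so these rates do not carry over to smaller lists, smaller differences or mismatched names. Among 200 simulated copies of exons the median covered share was 100%, and among 200 transcripts placed at random it was 47.7%.

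The rule for named genes fixed beforehand had parts that need a test of expression, which could not be applied. Its list of genes always to be named was kept, except for a gene that is not reported here. Other genes are named because they had the most transcripts, or as members of a list, and were chosen after their values were seen. Each transcript's credited sample was taken from the name in the file, which spells the sample titles with the letter O in place of the zero.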

Results

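The data describe the transcripts assembled from 8 samples of turkey breast muscle, 4 classed as normal and 4 as PSE. The study's question was which genes differ in expression between the 2 kinds of meat. The annotation merged over all samples held 162644 exon lines in 41982 transcripts and 23108 loci. It carries no measure of abundance and the depth of each sample is unknown here, so what follows is which genes were assembled and in what form, over both kinds of meat together. No level is compared between PSE and normal muscle.

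Of the 17 measurable genes of the tricarboxylic acid cycle, the central oxidative pathway of mitochondria, 16 were assembled (94.1%, exact 95% interval 71.3 to 99.9%), against 49.9% of all other genes. Among them were CS, the citrate synthase that opens the cycle, with 1 exact match among 2 transcripts, and SDHB, a subunit of succinate dehydrogenase, with 3. SDHD was the member without an assembled transcript under its symbol. The adjusted p was 0.00106 by Fisher's exact test. Of the 28 lists tested this way, 9 were assembled more often than other genes after Benjamini-Hochberg adjustment and 0 less often. At an unadjusted p under 0.05 the numbers were 12 and 0. A symbol absent from the annotation counts as not assembled, whether the gene was missing or only named otherwise. Of the 8208 gene names on any transcript, 7360 counted as assembled, so these shares largely reflect whether a symbol occurs in the annotation. When only exact matches to a reference transcript were counted, 3 of the 9 passed: the tricarboxylic acid cycle, the ubiquitin, proteasome and autophagy list and the ribosomal proteins.

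The genes of fatty acid use stood in 26 of 32 cases (81.2%, interval 63.6 to 92.8%, adjusted p = 0.00175 by Fisher's exact test). Their excess over other genes fell from 31.4 to 8.67 percentage points with only exact matches, where it was not called (adjusted p = 0.52, Fisher's exact test). ETFA, which passes electrons from fatty acid oxidation to the respiratory chain, had 8 transcripts, and PLIN2, a lipid droplet coat protein, had 5. FABP7, a fatty acid binding protein, was not assembled under its symbol.

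Ubiquitin ligases, proteasome subunits and autophagy genes were assembled in 43 of 51 cases (84.3%, adjusted p = 5.19e-06, Fisher's exact test). FBXO32 and TRIM63, muscle ubiquitin ligases known from atrophy, had 1 and 2 transcripts, all of them variants of the reference. Cytosolic ribosomal proteins followed with 52 of 64 (81.2%, adjusted p = 5.19e-06, Fisher's exact test). Endoplasmic reticulum stress genes reached 21 of 24 (87.5%, adjusted p = 0.00106, Fisher's exact test). With only exact matches the excess went from 37.6 to 9.7 percentage points and was not called (adjusted p = 0.52 by the exact test). HYOU1, a chaperone of that compartment, had 12 transcripts of at most 2 exons.

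Of 27 collagen and matrix genes, which are made mainly by fibroblasts, 21 were assembled (77.8%, adjusted p = 0.0127, Fisher's exact test). With only exact matches the direction turned, from 27.9 to -0.967 percentage points against other genes (adjusted p = 1 by the exact test). COL3A1 had 23 transcripts, 22 of them fragments contained in the reference transcript, and COL1A2 had 11. Endothelial and pericyte markers were assembled in 12 of 15 cases (80.0%), which missed the threshold at an adjusted p of 0.0589 by Fisher's exact test. Adipocyte markers stood at 8 of 11 and leukocyte and macrophage markers at 12 of 19, with adjusted p of 0.291 and 0.408 by the same exact test. With only exact matches the endothelial excess went from 30.1 to 13.9 percentage points and the leukocyte excess from 13.2 to 1.57. The adipocyte excess went from 22.8 to 26.0. None was called there (adjusted p = 0.409, 0.932 and 0.212, exact test). ADIPOQ and PLIN1, which mark fat cells, had 2 transcripts each, and C1QA, C1QB and C1QC, the complement genes of macrophages, had 1 each. Of 12 nerve and Schwann cell markers, 6 were assembled (adjusted p = 1, Fisher's exact test).

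Actin cytoskeleton genes (27 of 36, adjusted p = 0.00997), genes of insulin and growth factor signalling (21 of 26, adjusted p = 0.00689) and slow fibre sarcomere genes (11 of 13, adjusted p = 0.0398) completed the lists above the rest by Fisher's exact test. MYL2, TNNC1 and MB, which belong to slow or oxidative fibres, had 1 transcript each. With only exact matches the actin excess went from 25.1 to 11.1 percentage points and the insulin excess from 30.9 to 3.6, and neither was called (adjusted p = 0.3 and 0.87, exact test). The actin call also ended when every class was counted, where the excess was 19.9 percentage points (adjusted p = 0.0509, exact test). The slow fibre call did not hold under 4 of the 5 alternatives tried, with adjusted p between 0.0627 and 0.521 by Fisher's exact test. In 3 of the 4 the excess was 29.5 to 34.6 percentage points, against 34.7 as reported, and with only exact matches it was 11.3. In the fast fibre list only 6 of the 22 members had a measurable symbol, of which 3 were assembled. These were PVALB, the calcium-binding parvalbumin, with 3 transcripts, and TNNI2 and MYOZ1, with 2 each (adjusted p = 1, Fisher's exact test). The other measurable members, MYL1, TNNT3 and TNNC2, had no locus under their symbols. Whether the annotation holds them under other names is unknown here.

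The 4 lists closest to the textbook questions about PSE meat (calcium handling, glycogen, glycolysis and control of pyruvate dehydrogenase) did not differ detectably from other genes. Excitation-contraction coupling and calcium handling stood at 23 of 38 (60.5%, interval 43.4 to 76.0%, adjusted p = 0.366 by Fisher's exact test). Glycogen metabolism stood at 15 of 24 (62.5%, interval 40.6 to 81.2%, adjusted p = 0.376) by the same exact test, and glycolysis at 13 of 21 (61.9%, interval 38.4 to 81.9%, adjusted p = 0.42). The glycolysis members GAPDH, TPI1, PGAM1 and PKM were measurable but had no locus under their symbols, so they counted as not assembled. Whether the annotation holds GAPDH, TPI1 and PGAM1 under other names is unknown here. Control of pyruvate dehydrogenase stood at 7 of 12 (58.3%, interval 27.7 to 84.8%, adjusted p = 0.677, Fisher's exact test). Its difference from other genes was 8.41 percentage points, and 24.99 with older and newer symbols joined (adjusted p = 0.292 by the exact test), where BRP44L and BRP44 stood for MPC1 and MPC2. With only spliced transcripts it was 1.45. The glycogen difference from other genes was 12.6 percentage points, 22.6 with other same-strand overlaps and single exons reaching into introns added, and 1.35 with only exact matches, and was not called under any of them (adjusted p = 0.376, 0.0831 and 0.932, exact test). For calcium handling the difference was 10.6 percentage points, and 1.57 with only exact matches. The intervals of these 4 lists all include the 49.9% of other genes and are wide, so they leave room for a moderate difference. How large a difference could be detected with these numbers of genes was not computed. Other sarcomere and Z-disc genes stood at 17 of 25 (adjusted p = 0.161), heat shock genes and chaperones at 25 of 37 (0.0771), and hypoxia response genes at 13 of 17 (0.0771), all by Fisher's exact test. The sarcomere and Z-disc difference was 18.1 percentage points, and 4.53 with only exact matches. ACTA1 and TTN of that list also had no locus under their symbols and counted as not assembled. The calls for heat shock and hypoxia genes depended on the setting. Heat shock genes were called with other same-strand overlaps and single exons reaching into introns added and with every class (adjusted p = 0.0405 and 0.0439, exact test). Hypoxia genes were called with older and newer symbols joined (32.4 percentage points, adjusted p = 0.0394, exact test). Creatine and adenine nucleotide buffering stood at 10 of 15 (0.366), the calpain system at 6 of 9 (0.436) and immediate-early genes at 11 of 18 (0.436), by the same exact test. The immediate-early difference was 11.2 percentage points, and between 1.45 and 28.2 over the alternatives, where it was not called. Satellite cell and myogenic regulators stood at 7 of 14 and antioxidant genes at 14 of 28, both with an adjusted p of 1 by that exact test. The 2 lists with a lower share than other genes were nuclear oxidative phosphorylation, at 19 of 46 (41.3%, adjusted p = 0.421), and the circadian clock, at 6 of 17 (35.3%, adjusted p = 0.436), by Fisher's exact test. The measurable oxidative phosphorylation members were NADH dehydrogenase subunits (NDUF symbols) and ATP synthase genes under newer names. All 19 assembled ones were NDUF genes, and none of the newer ATP synthase names was assembled. No UQCR or COX symbol was measurable, although some, such as UQCRC1 and COX5A, were assembled. The share therefore does not describe the whole pathway. The direction of the oxidative phosphorylation list was not stable. It went from -8.66 percentage points against other genes to 8.7 with older and newer symbols joined, as ATP synthase genes such as ATP5B and ATP5C1 were assembled under their older names, and to 8.81 with only exact matches (adjusted p = 0.409 and 0.382, exact test). The clock difference went from -14.7 to -1.84 percentage points with only exact matches and to -5.37 with other same-strand overlaps and single exons reaching into introns added. PER3, NR1D2 and TEF were among the assembled clock genes. Mitochondrially encoded genes and red blood cell markers had too few measurable symbols and were not tested. No line lay on a sequence named for the mitochondrion.

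**Figure D1:**
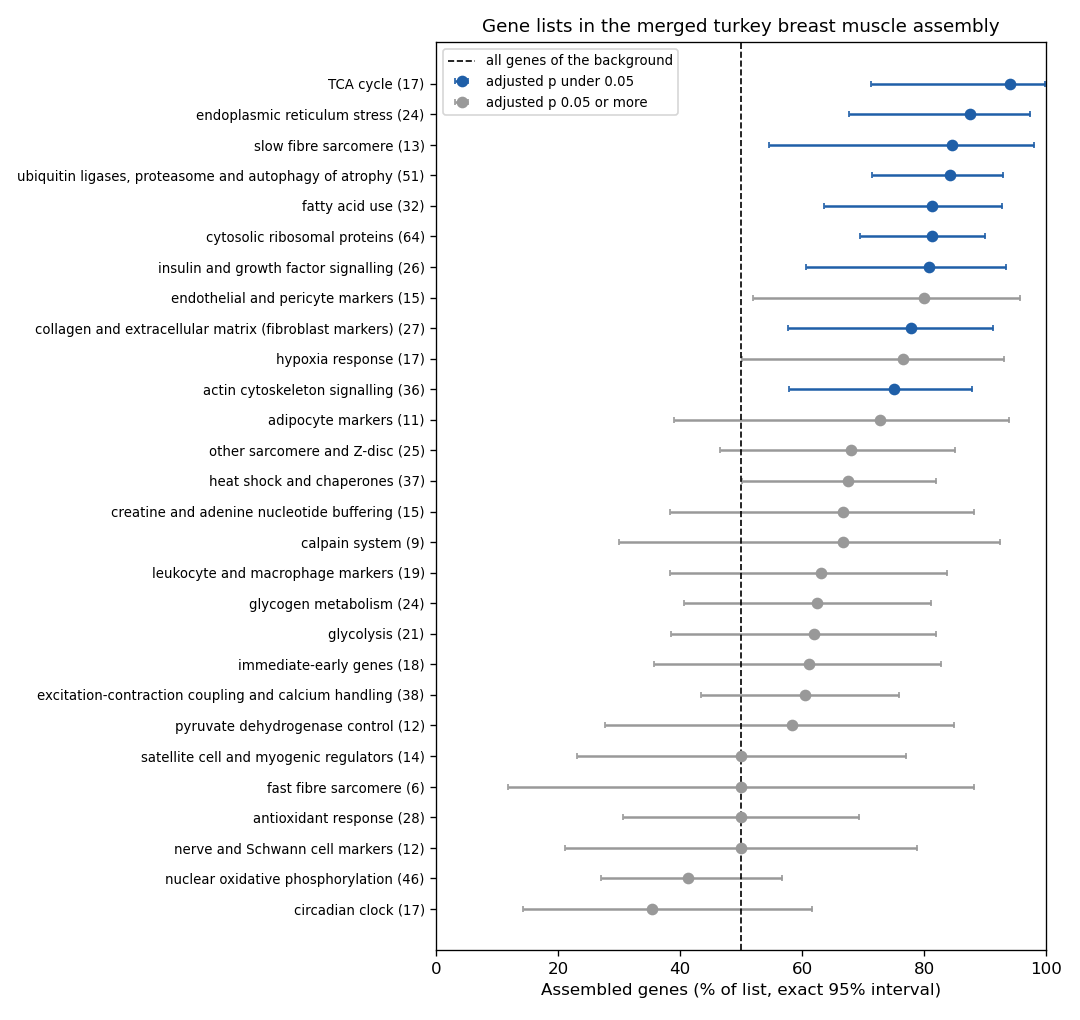
Share of each gene list's measurable members (number in brackets) that had an exact, contained or variant transcript, in % on the horizontal axis, with exact 95% intervals as bars. The dashed line marks the 49.9% of the whole background; the 9 lists in blue passed an adjusted p of 0.05, led by the tricarboxylic acid cycle at 94.1%.

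Of the genes that were to be named whatever their values, 6 were assembled under their symbols. PDK4, a kinase that shuts off pyruvate dehydrogenase, had 1 transcript of 11 exons, a variant of the reference, on chromosome 6 from 24183113 to 24192720 on the minus strand. RYR3, a calcium release channel of the sarcoplasmic reticulum, had 11 transcripts (9 variants and 2 contained fragments) in 1 locus on chromosome 5 from 31262992 to 31428512, minus strand, the longest chain having 30 exons. CASQ2, a calcium-binding protein of that store, had 1 exact match and 1 variant of up to 11 exons on chromosome 1 from 84188644 to 84218132, plus strand. PRKAG3, the muscle subunit of AMP-activated kinase, had 3 variants of up to 13 exons on chromosome 7 from 23624088 to 23628982, minus strand. FBXO32 had 1 variant of 8 exons on chromosome 3 from 88785330 to 88806303, minus strand. HSPA8, the constitutive heat shock protein, had 2 variants and 1 contained fragment of up to 9 exons on chromosome 26 from 3255911 to 3261309, plus strand. RYR1 was in the background and counted among the calcium handling genes as not assembled, with no locus under its symbol. Whether the annotation holds it under another name is unknown here. ATP2A1, PYGM, LDHA and MYH7 were outside the background and had no transcript under those symbols, and they were not analysed here.

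Variant transcripts, which share a junction with a reference transcript and differ elsewhere, numbered 8096 and were 19.3% of all transcripts. Contained fragments numbered 6980 (16.6%) and exact matches 3411 (8.12%). Among the 5815 assembled genes of the background, 3029 (52.1%) had at least 1 variant. The list members with the most variants were chosen after their values were seen. NEB, the nebulin of the thin filament, had 12 variants among 53 transcripts on chromosome 7 from 38025769 to 38107977. MYPN, a Z-disc protein, and RYR3 had 9 each, and COL6A3 and DMD had 7 each. In NEB, 41 of the 53 were contained fragments and the longest chain had 11 exons, so most of these entries covered part of the gene.

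By list, 18 of 23 calcium handling genes had a variant (78.3%, interval 56.3 to 92.5%) against 52.0% of other genes. Collagen and matrix genes followed with 16 of 21 (76.2%). Neither passed adjustment over the 27 lists tested (adjusted p = 0.324 and 0.392, Fisher's exact test), so 0 lists were called and 2 stood at an unadjusted p under 0.05. Classing genes by the most exons on any assembled transcript, itself a product of the assembly, left 0 lists called as well. Calcium handling had an adjusted p of 0.169 there by the Mantel-Haenszel test. The difference was then 25.9 percentage points for calcium handling, against 26.3 before, and 13.7 for collagen and matrix genes, against 24.2 before. Glycolysis genes had the variant in 4 of 13 cases (30.8%, adjusted p = 0.638, Fisher's exact test).

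A gene name stood on 15277 loci (66.1%), and 7831 had none. Single-exon transcripts made up 20119 of the 41982 (47.9%). Transcripts with no class (a dot) numbered 10839 (25.8%). The ones among them that also had no nearest reference transcript numbered 8414, and the others had such a reference, so a dot does not mark a transcript as unknown. Of the 8414, 1435 were spliced, in 1134 loci. Loci made only of transcripts with no class, at least 1 of them spliced, numbered 1055. Transcripts on the opposite strand of an exon numbered 4293 (10.2%), those inside introns 3174 (7.56%), and those close to a gene 2342 (5.58%). Of the gene names, 2566 (31.3%) stood on 2 or more loci when every class was counted, and 1 did when only exact, contained and variant transcripts were. A further 228 loci carried 2 or more gene names. The locus with the most transcripts, XLOC_033120 on chromosome 7 from 15545232 to 15693105, plus strand, had 76 transcripts and no gene name. Of these, 34 were contained in a reference transcript and 6 were variants, so a missing gene name did not mean a missing reference there.

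Of the transcripts on the opposite strand of an exon, 3972 had a single exon and 3564 of these touched an exon of a spliced transcript. Exons on the other strand covered a median 98.4% of their length (quartiles 94.9 to 100%). For the mean of 20 random placements of each on the same exon, the median was 51.3% (quartiles 45.1 to 57.1%). The latter quartiles are of means and do not give the spread of single placements.

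**Figure D2:**
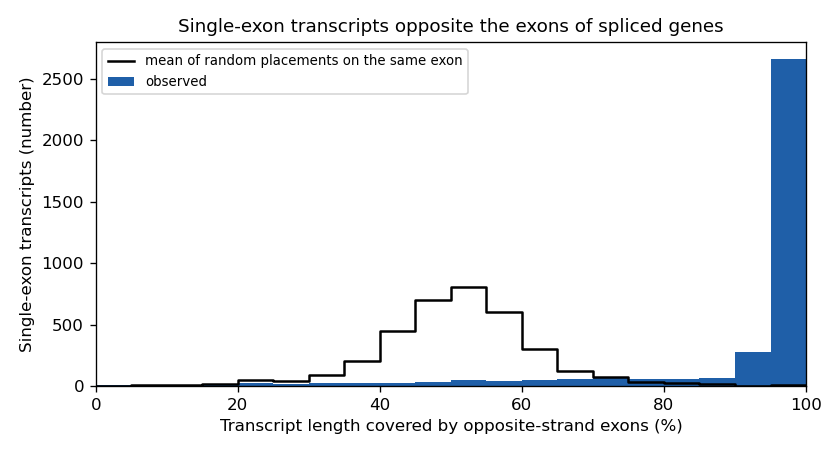
Share of each single-exon opposite-strand transcript that lies within exons of spliced transcripts on the other strand (horizontal axis, %), as number of transcripts (vertical axis). Bars are the 3564 observed transcripts, with a median of 98.4%, and the line is the mean over 20 random placements of each, with a median of 51.3%.

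The sample credited with each transcript was very uneven. The 4 normal samples were credited with 20486, 9486, 4651 and 3119 transcripts and the 4 PSE samples with 2337, 1165, 689 and 49, in the order of their replicate numbers. Normal samples together held 37742 (89.9%) and PSE samples 4240 (10.1%). The normal samples differed among themselves by 6.57 times, so the gap between the groups was not set against a spread between replicates, and no test was made. Exact matches numbered 2158, 613, 214 and 108 in the normal samples and 115, 57, 97 and 49 in the PSE samples. PSE replicate 4 was credited with exact matches only.

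**Figure D3:**
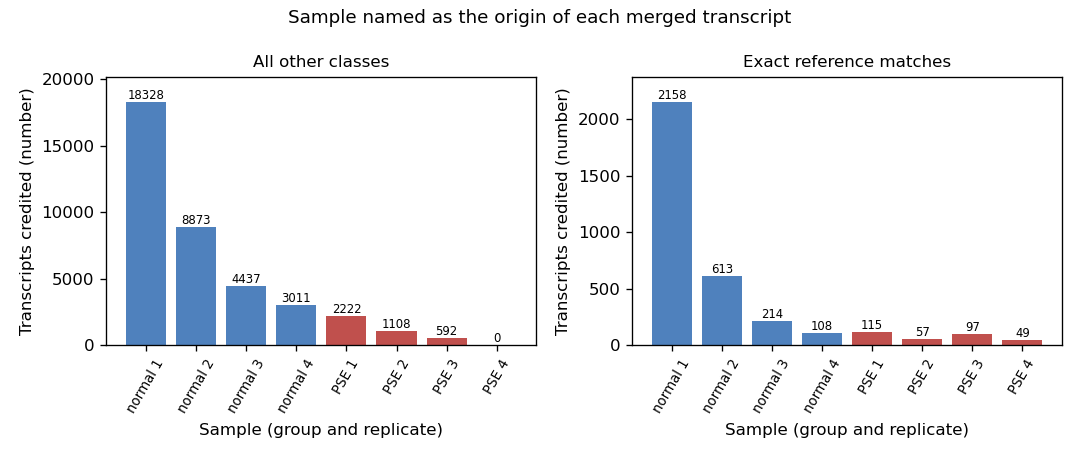
Number of merged transcripts credited to each sample (vertical axis), for exact reference matches and for all other classes; bars are single samples, blue for normal and red for PSE, and carry no error. Other transcripts go from 18328 in normal replicate 1 to 0 in PSE replicate 4.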

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

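All tests in this part were chosen after the pattern was seen. The annotation held 4293 transcripts on the opposite strand of an exon, a class left out of the comparisons of gene lists except where every class was counted. They stand out as a signal outside the main measurement. Of these, 3972 (92.5%) had a single exon, and 3564 touched an exon of a spliced transcript on the other strand. They copied those exons almost end to end. Their median length was 176 bases against 170 for the exon, and the median offset was 0 bases at both ends (quartiles -3 to 7 and -4 to 7). Opposite exons covered a median 98.4% of each, against 51.3% for the mean of its 20 random placements on the same exon. The gene with the most was TRIP12 with 24, followed by RYR3 with 23, UBR4 with 22 and CLTCL1 with 20. Of the list members, COL6A3 had 16 and CAPN1, a calpain protease, had 12. These genes were chosen after their values were seen.

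Antisense transcription with ends unrelated to the exons is argued against. Of the 3564, 98.8% (exact 95% interval 98.4 to 99.1%) were covered more than the mean of their random placements. The interval takes transcripts as independent, but those with a gene name lay in 914 genes, so it is likely too narrow. Reads of the spliced gene placed on the wrong strand remain a candidate explanation. The median cover of 98.4% goes with it but does not test it, since that value had been seen before the explanation was stated. Of the 20119 single-exon transcripts of all classes, 7378 carried no strand. The strand protocol is not given, so how the others came by a strand is unknown here. Antisense RNA that itself has the length of the opposite exons was not tested and stays open, and no difference between PSE and normal muscle was tested for these transcripts. The 3564 transcripts form part of 3373 loci (14.6% of all loci), so under the wrong-strand hypothesis a count per locus could hold reads of a gene under a second identifier.

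Transcripts on chromosome W, the female-specific sex chromosome of birds, numbered 6 and stand out as a signal that no comparison was about. They formed 2 loci and were credited to normal replicates 1 and 2, which were credited with 48.8% and 22.6% of all transcripts. The sex of the birds is not in the labels used here, and no explanation was tested.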

How the results depend on the processing

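Alternatives chosen before the data were examined (other normalizations, filters, tests, summed loci and leaving out each sample) were not run, since each needs counts tied to samples. No paired analysis was possible because no column of values could be tied to a sample, and so no replicate number could enter a fit. The alternatives given here were all added after seeing the data. Requiring an exact match lowered the assembled gene names from 7360 to 2849, by construction, and the lists above the rest from 9 to 3, where the cause was not tested; there the collagen and matrix list reversed to -0.967 percentage points against other genes. The lists of fatty acid use, endoplasmic reticulum stress, slow fibre, actin cytoskeleton and insulin signalling kept their direction there but were no longer called. The nuclear oxidative phosphorylation list, not called, turned from -8.66 to 8.81 points there and to 8.7 with older and newer symbols joined. With other same-strand overlaps and single exons reaching into introns added, with every class, with only spliced transcripts or with older and newer symbols joined, 8 or 9 lists stood above the rest and 0 below. The slow fibre list lost its call in 3 of these 4 and the actin cytoskeleton list under every class (adjusted p = 0.0509, Fisher's exact test), while heat shock genes gained one in 2 and the hypoxia list in 1. The actin excess was then 19.9 percentage points, against 25.1 as reported. For heat shock genes it was 20.6 in both settings, against 17.7, and for hypoxia genes 32.4, against 26.6. In the test for variant transcripts, all 27 lists stayed on the same side of the threshold under both alternatives. Loci with a gene name rose from 66.1% to 77.1% when only loci with a spliced transcript were counted. The median cover of opposite-strand transcripts was also 98.4% against transcripts of 4 or more exons. Depth is unknown here, so an unassembled gene cannot be called unexpressed.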

Other observations

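All tests in this part were chosen after the pattern was seen. In 1121 loci every transcript was credited to a PSE sample. Spliced exact, contained or variant transcripts of these loci named 82 genes that had no such transcript credited to a normal sample. The 82 included HAS2, a hyaluronan synthase, DDR2, a collagen receptor, LYVE1, a lymphatic vessel marker, FGF10 and FGF18, which are growth factors, and AGRN, the agrin of the neuromuscular junction. These 6 were chosen after the names were seen, and the 82 were not tested for a shared theme. None of the 82 was in a gene list, which was not tested either. With only spliced transcripts counted, 7142 gene names were assembled, and 10.1% of all transcripts were credited to PSE samples. Which sample a transcript is credited to is not a level of expression, as the next paragraph weighs.

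Credited transcripts fell at 7 of 7 steps from normal replicate 1 to PSE replicate 4, in the order of the labels. Fewer transcripts in PSE muscle are argued against as the whole cause, since the highest normal sample exceeded the lowest by 6.57 times within 1 group. Whether a transcript is credited to the first sample assembly that holds it stays open, since the fall at 7 of 7 steps is the pattern itself. Exact matches taken alone fell at 5 of the 7 steps and rose at 2, from 108 to 115 and from 57 to 97. These rises do not decide about crediting to the first assembly, which does not fix how many transcripts each later sample adds. A smaller difference between the groups stays open.

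PSE replicate 4 was credited with 49 of 3411 exact matches and 0 of 38571 other transcripts. A rule by which transcripts without an exact reference match were kept only if 2 or more assemblies held them, and a failed assembly of that sample, cannot be told apart here: the 0 and the 49 are the observation itself, and no other value tests either. The curation rule is not given in the sources used here.

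Single-exon transcripts of exactly 55 bases, the shortest length present, numbered 810, of which 677 lay inside an intron; the next most frequent length, 112 bases, had 63. Single-exon transcripts with a strand lay on the plus strand in 7563 cases and on the minus strand in 5178, while spliced transcripts were split 11176 to 10687. A further 7378 single-exon transcripts had no strand.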
